A study of Mus musculus with 15 samples.

How the data were processed

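The values analysed were TPM per gene for 15 libraries, as deposited by the authors, from the cortex of wild-type male mice at postnatal day 28: 5 libraries each of magnetically isolated neurons, astrocytes and microglia. Per the labels, RNA was purified on columns, cDNA was made from polyA RNA and amplified by PCR, and libraries were sequenced on a NovaSeq at an average of 30000000 reads of 2 x 150 nt. Per the submitters' processing notes, Trim Galore 0.6.4, STAR 2.7.1a, RSEM 1.2.28 and DESeq2 1.36.0 were used with the mm10 genome. The TPM table keeps no read depth and gives no values per exon, so depth per library and exon inclusion could not be computed. Every column summed to 1000000 TPM within rounding, all 15 columns were used, and no pair of libraries held identical values. Of the genes, 1518 were at 0 in all libraries, 63 rows shared a symbol with another row, and none was a mitochondrially encoded gene. The table held 100 genes of ribosomal proteins. Gene coordinates are those of GENCODE vM21 on mm10, which held 20499 of the gene IDs.

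Values were taken as log2(TPM + 1) with a pseudocount of 1, and 13351 genes with at least 1 TPM in at least 5 libraries were tested. One linear model with a mean per cell type was fitted to all 15 libraries in limma 3.58.1, with moderated variances that follow mean expression. A gene was called different when its Benjamini-Hochberg adjusted p was below 0.05 and its log2 difference at least 1, and enriched in a cell type when called higher there than in both others. The analysis used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The model, the thresholds, the gene lists, the rule for naming genes and the alternatives other than 5 named in the sensitivity section were set before the data were examined.

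For gene groups, 38 lists were written from general knowledge (14 of cell type markers and 24 of functions), and 37 had enough tested genes for camera, a test of whether a list differs from the other genes, with a preset correlation of 0.01 between genes. Adjustment was over the 111 tests of 37 lists in 3 comparisons, of which 71 had an adjusted p below 0.05. With the correlation estimated from each list 7 did, and with fry, which tests whether a list's genes move on balance one way, 97 did. Red blood cell markers had 1 gene in the table, Alas2, and were not tested as a list. Counts of changed members were also made with the adjustment over the list alone.

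Genes named in the text are, by rule, the enriched genes of each cell type and the called genes of each comparison with the largest differences and no overlap between groups. To these come, for each list, up to 4 members with the largest differences and any that go against the list, and members of the DNA methylation and splicing lists. Within that rule 151 symbols were picked after the values were seen. Results for some of these genes are not reported here. Paralogs and pseudogenes share reads, so values of Ly6c1, Ly6c2, Ly6a, Hbq1a and ribosomal proteins are uncertain. Replicate numbers are shared between the cell types, and a check from the data alone compared libraries of one number after removal of group means. All 5 correlations between neurons and microglia were above 0.1 (0.216 to 0.382), so by the preset rule the numbers pair these libraries, while those for neurons and astrocytes (-0.0329 to 0.233) and astrocytes and microglia (-0.0110 to 0.249) did not all pass. The pairing is evidence from the data and is not stated in the labels.

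Alternatives were a pseudocount of 0.1, no filter, a stricter filter of 5 TPM, median-of-ratios scaling, quantile normalization, removal of ribosomal protein genes, fits of 2 groups at a time, array weights, no variance trend, the replicate number as a block, the estimated correlation, fry, each library left out in turn, and 5 added later. In a self-test on simulated values for the same genes and groups, 94, 97 and 90 of 100 genes changed by a log2 of 1.5 and 100, 100 and 99 of 100 changed by 3 were recovered for neurons against astrocytes, neurons against microglia and astrocytes against microglia. Unchanged genes called were 2, 1 and 5. A simulated list of 20 genes shifted by a log2 of 1 in neurons passed in both comparisons with neurons, and random lists passed in 0 of 600 tests. The simulated genes varied independently, so this gives no rate of false calls for lists whose genes are correlated. Changed genes were drawn only from those with a mean log2(TPM + 1) above 2, so recovery at lower levels was not measured. No difference by replicate number was simulated.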

Results

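Gene expression was compared between neurons, astrocytes and microglia isolated magnetically from the cortex of wild-type male mice at postnatal day 28, with 5 polyA RNA-seq libraries for each cell type (n = 5, 15 libraries in all). The comparison asked which genes, regulators of DNA methylation and splicing regulators set the 3 cell types apart. Of the genes in the deposited TPM table, the 13351 with at least 1 TPM in at least 5 libraries were tested. No label ties a library to an animal, so p-values here measure the spread between libraries, whether technical or biological. Folds were taken on the log2(TPM + 1) scale, which understates differences of genes with few transcripts.

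Marker transcripts separated the libraries by their labelled cell type. The 24 microglia markers summed to 137582 ± 27016 TPM in microglia (mean ± SD, n = 5), 212 ± 43.5 in neurons and 353 ± 51.4 in astrocytes. The 22 astrocyte markers summed to 46072 ± 2624 TPM in astrocytes, 1482 ± 220.3 in neurons and 1933 ± 385 in microglia. The 18 pan-neuronal markers reached 2539 ± 586 TPM in neurons, 570.0 ± 217 in astrocytes and 187 ± 132 in microglia. Excitatory neuron markers summed to 367 ± 121, 188 ± 14.9 and 58.4 ± 29.4 TPM in neurons, astrocytes and microglia, and inhibitory neuron markers to 908 ± 472, 374 ± 67.1 and 40.5 ± 25.2.

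Transcripts of other brain cells were measured in each isolate as well. In the neuron libraries the 13 endothelial markers summed to 32729 ± 5025 TPM, against 2507 ± 263 in astrocytes and 597 ± 193 in microglia. Most of that neuron sum was Ly6c1 (20119 to 31922 TPM per library), whose reads are uncertain. The 11 mural cell markers summed to 4281 ± 1104 TPM in neurons, 2266 ± 311 in astrocytes and 179.7 ± 67.6 in microglia. Mature oligodendrocyte markers summed to 27485 ± 31445 TPM in microglia, with a range of 255 to 69940 between libraries, and to 4201 ± 4865 in neurons and 1482 ± 1358 in astrocytes. Border macrophage markers summed to 1457 ± 257 TPM in microglia, 47.9 ± 9.10 in neurons and 63.4 ± 12.9 in astrocytes. Alas2, the heme synthesis enzyme of red cell precursors, was at 451 ± 315 TPM in neurons, 7.41 ± 2.23 in astrocytes and 3.04 ± 2.05 in microglia.

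**Figure D1:**
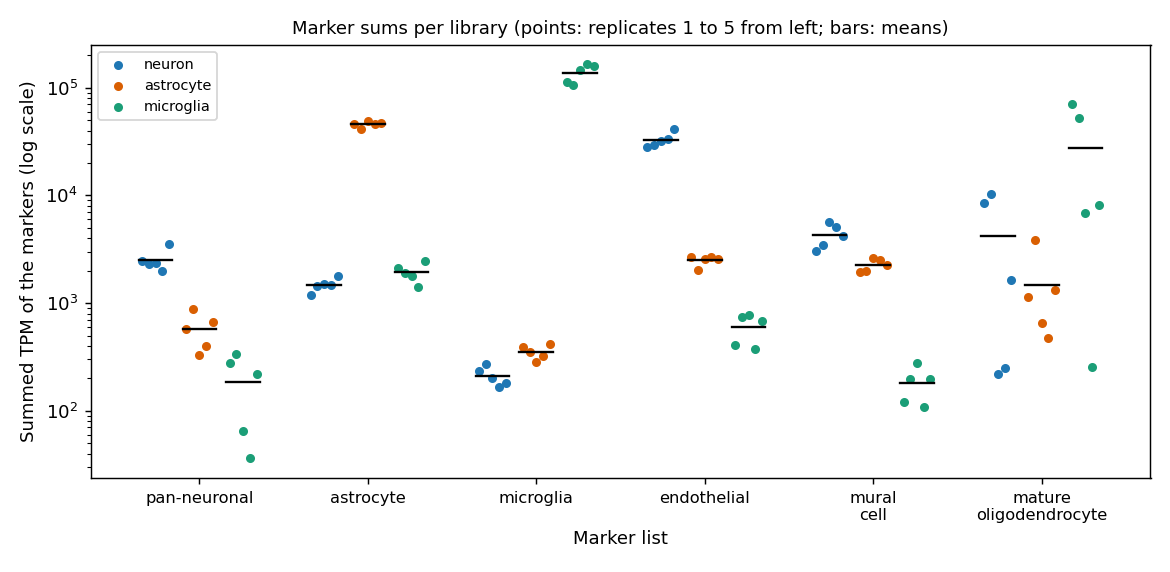
Summed TPM of 6 marker lists in the 15 libraries, on a log axis. Points are replicates 1 to 5 from left to right within each cell type, and bars are means.

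The cell types also separated across all tested genes. Principal component 1 held 62.5% of the variance and parted microglia from the other cells, and component 2 held 24.6% and parted neurons from astrocytes. On component 3 (5.09%) libraries numbered 1 and 2 lay opposite to those numbered 3 and 4 in every cell type. Pearson correlations of log2(TPM + 1) were 0.964 to 0.987 among neuron libraries, 0.970 to 0.987 among astrocyte libraries and 0.933 to 0.989 among microglia libraries. Between cell types they were 0.830 to 0.871 for astrocytes and neurons, 0.666 to 0.793 for microglia and neurons, and 0.675 to 0.768 for astrocytes and microglia. Neuron libraries held 12592 ± 241 genes at 1 TPM or more, astrocyte libraries 12505 ± 479 and microglia libraries 10946 ± 213. The 10 most abundant genes took 18.8 ± 2.73% of all TPM in neurons, 22.6 ± 1.05% in astrocytes and 31.9 ± 1.64% in microglia.

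**Figure D2:**
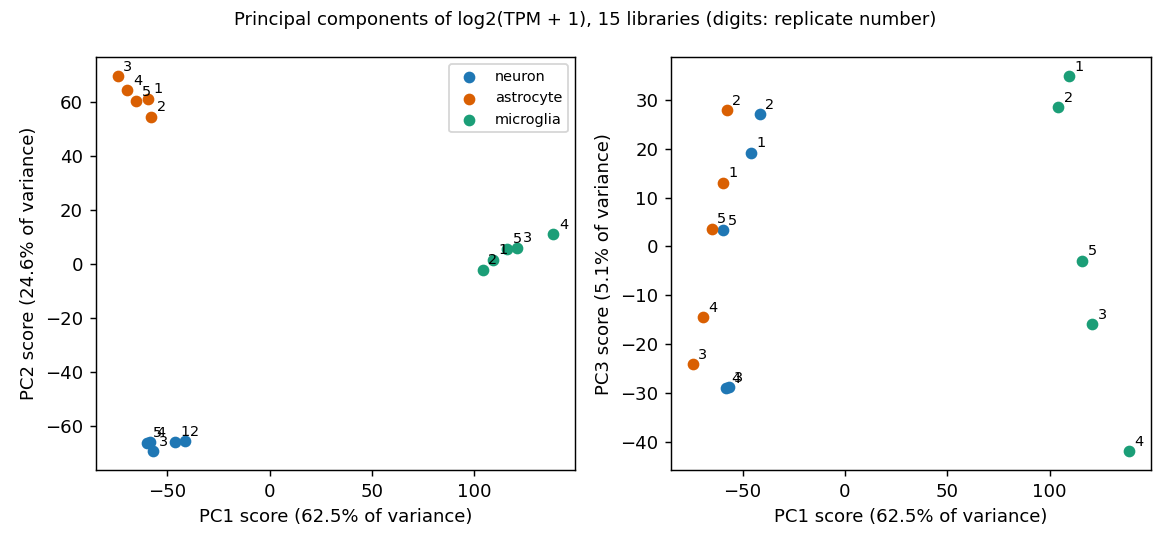
Principal components of the 13351 tested genes, component 1 against component 2 and against component 3. Points are libraries, coloured by cell type and marked with the replicate number.

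The genes higher in neurons than in astrocytes included Penk, Tac2, Npy, Cck, Stmn2 and Snap25. Penk (chr4:4133531-4138819, mm10), the precursor of the enkephalins, was at 139 ± 63.0 TPM in neurons and 3.92 ± 1.43 in astrocytes (27.2-fold, adjusted p = 1.29e-09). Tac2, the neurokinin B precursor, was at 37.4 ± 19.4 and 0.878 ± 0.615 (18.8-fold, adjusted p = 8.25e-09). Npy was at 581 ± 335 and 44.7 ± 11.4 TPM (11.5-fold), and Cck at 913 ± 449 and 67.1 ± 41.4 (14.0-fold). Stmn2, a regulator of microtubules in growing axons, was at 188 ± 57.5 and 15.3 ± 5.56 (11.6-fold). Snap25, a SNARE protein of vesicle fusion, was at 475 ± 193 and 54.7 ± 25.1 TPM (8.74-fold, adjusted p = 6.44e-05). Vascular transcripts stood among the largest differences in the same direction. Ly6c1 (chr15:75044018-75048830) was at 23317 ± 4855 TPM in neurons and 1422 ± 176 in astrocytes (16.2-fold), and the tight junction gene Cldn5 at 1489 ± 418 and 184 ± 43.2 (adjusted p = 3.17e-09). Reads of Ly6c1 cannot be fully parted from those of its neighbours Ly6c2 and Ly6a, which were also higher in neurons (20.1-fold and 15.6-fold). The largest fold in favour of neurons was that of Alas2 (47.2-fold, adjusted p = 1.46e-09).

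The genes higher in astrocytes than in neurons included Ntsr2, Aldoc, Slc7a10 and Slc1a3. Ntsr2, a neurotensin receptor, was at 2765 ± 277 TPM in astrocytes and 11.3 ± 8.13 in neurons (log2 difference of -8.06, neuron minus astrocyte, adjusted p = 1.31e-12). The glycolytic enzyme Aldoc (chr11:78322968-78327781) was at 14959 ± 794 and 89.7 ± 76.4 (-7.88, adjusted p = 3.67e-10). Slc7a10 (chr7:35186385-35201114), a transporter of neutral amino acids, was at 648 ± 98.9 and 2.21 ± 1.01 TPM (-7.71), and Slc1a3, which clears glutamate from the synaptic space, at 2142 ± 534 and 18.1 ± 3.07 (-6.79). Apoe, a lipid carrier, was at 52341 ± 3705 TPM in astrocytes and 2290 ± 425 in neurons (-4.53). Msmo1, an enzyme of cholesterol synthesis, was at 1475 ± 251 and 39.6 ± 4.77 TPM (-5.17). Among transcription factors, Dbx2 (-5.79), Hopx (-5.21), Id4 (-5.04) and the Notch target Hes5 (-4.17) were higher in astrocytes.

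In total 3412 genes differed by at least 2-fold at an adjusted p below 0.05, 1722 higher in neurons and 1690 higher in astrocytes. At least 8-fold differences were seen for 49 genes in favour of neurons and 262 in favour of astrocytes. Leaving out all libraries numbered 1 and 2 gave 1765 and 1777 genes, and leaving out those numbered 3 and 4 gave 1761 and 1665.

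Several lists of neuronal genes were higher in neurons than in astrocytes. Counts of list members adjusted over the list alone are given where they differ from those adjusted over all genes, and every list p is from camera with a preset correlation of 0.01 unless stated. Of 18 pan-neuronal markers 14 were higher in neurons, or 15 adjusted over the list alone (median log2 difference 2.11, adjusted p = 4.41e-05, and adjusted p = 0.417 with an estimated correlation). Of 22 genes of synaptic vesicle release machinery 14 were higher, or 15 adjusted over the list alone (adjusted p = 6.48e-05, and adjusted p = 0.417 with an estimated correlation). The exception was Syngr1, a vesicle protein lower in neurons (18.9 ± 2.77 TPM against 78.7 ± 6.63 in astrocytes). Inhibitory neuron markers were higher for 10 of 16 genes and lower for 1 (adjusted p = 1.38e-04, and adjusted p = 0.320 with an estimated correlation). Voltage-gated sodium, potassium and calcium channels were higher for 6 of 16 genes and lower for 1 (adjusted p = 0.0163, and adjusted p = 0.502 with an estimated correlation). Scn2a was at 8.89 ± 3.14 and 2.53 ± 0.821 TPM, and the list's call ended after correction for transcript length and GC content with the replicate block (adjusted p = 0.0508). In the same neuron libraries all 13 endothelial markers were higher (median 2.60, adjusted p = 1.72e-10, and adjusted p = 0.164 with an estimated correlation).

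Neuronal transcription factors were higher in neurons for 6 of 10 genes and lower for 1. The higher ones included Dlx1 (18.5 ± 7.03 TPM against 2.55 ± 0.930) and Myt1l (41.6 ± 7.54 against 6.82 ± 1.06). The list passed (adjusted p = 0.00121, and adjusted p = 0.264 with an estimated correlation). Excitatory neuron markers were split and did not pass as a list (adjusted p = 0.164, and 0.0163 without the filter), with 6 of 15 higher in neurons, such as Neurod6 (12.2 ± 4.71 against 1.09 ± 0.621 TPM). The 3 lower ones included the layer markers Rorb (1.18 ± 0.266 against 17.9 ± 5.35) and Fezf2 (1.85 ± 0.606 against 13.6 ± 3.01). Ionotropic glutamate and GABA receptors were split as well (adjusted p = 0.0681, 0.0184 without the filter and 0.0382 without neuron 2), with 11 of 23 higher in neurons, including Grin2b (73.3 ± 43.0 against 11.8 ± 6.84 TPM). Gabrg1 (1.26 ± 0.313 against 58.3 ± 13.4) and Gabrb1 (10.3 ± 1.66 against 119.6 ± 27.4) were among 3 lower. These neuronal transcripts were measured in libraries whose endothelial sum exceeded their pan-neuronal sum (32729 ± 5025 against 2539 ± 586 TPM).

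Astroglial lists were lower in neurons. All 22 astrocyte markers were lower (median -5.45, adjusted p = 1.43e-20, and adjusted p = 0.0411 with an estimated correlation). All 16 genes of glutamate, potassium and water handling were lower (median -4.19, adjusted p = 3.80e-14, and adjusted p = 0.0790 with an estimated correlation). The water channel Aqp4 was at 537 ± 202 TPM in astrocytes and 7.34 ± 1.64 in neurons. Cholesterol synthesis was lower for 17 of 18 genes (median -2.40, adjusted p = 3.08e-08, and adjusted p = 0.320 with an estimated correlation). Sqle was at 99.5 ± 20.2 TPM in astrocytes and 10.1 ± 1.72 in neurons, and the exception was Ebp (30.4 ± 1.83 and 46.7 ± 8.84). Fatty acid oxidation was lower for 7 of 16 genes (median -0.95, adjusted p = 7.39e-06, and adjusted p = 0.346 with an estimated correlation), including Hadhb (73.3 ± 11.5 TPM in neurons, 263 ± 21.4 in astrocytes). Astroglial transcription factors were lower for 11 of 16 genes (adjusted p = 4.97e-08, and adjusted p = 0.133 with an estimated correlation). Glycolysis was lower for 5 of 17 genes (adjusted p = 0.00423, and adjusted p = 0.459 with an estimated correlation), such as Pfkm (18.9 ± 5.04 and 109 ± 15.2 TPM). Eno2, the neuronal enolase, was higher (50.4 ± 21.7 and 9.23 ± 3.82). Nuclear-encoded oxidative phosphorylation did not pass (adjusted p = 0.103), but did with quantile normalization (0.00264), without the filter (0.0163) and without astrocyte 3 (0.0466). It had 1 of 26 genes lower, Uqcrfs1 (165 ± 24.6 and 416 ± 5.62 TPM), and 1 higher only when adjusted over the list alone.

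Lists of microglial and other cell type genes gave mixed results between neurons and astrocytes. Microglia markers were lower in neurons for 6 of 24 genes (median -0.69, adjusted p = 0.00633, and adjusted p = 0.564 with an estimated correlation), among them C1qc (14.5 ± 4.34 against 34.0 ± 8.44 TPM). Complement, Fc receptors and phagocytosis genes were lower for 7 of 19 (adjusted p = 0.00139, and adjusted p = 0.417 with an estimated correlation). Among them were the phagocytic receptors Mertk (3.07 ± 0.728 against 56.3 ± 15.2) and Axl (17.1 ± 4.60 against 42.4 ± 9.01). Lysosome genes were lower for 8 of 21 (adjusted p = 0.00123, and adjusted p = 0.502 with an estimated correlation), with Ctsh higher in neurons (544 ± 111 against 101 ± 18.4). Border macrophage markers were lower for 1 of 9 (adjusted p = 0.0356, and adjusted p = 0.459 with an estimated correlation). This call ended without neuron 4 (adjusted p = 0.0651) or astrocyte 1 (0.0512), 2 (0.0639) or 5 (0.0581), under the stricter filter (0.0506) and with 2 scalings (0.0532 and 0.0636). Oligodendrocyte precursor markers were higher for 6 of 12, or 4 adjusted over the list alone (adjusted p = 0.0345, and adjusted p = 0.565 with an estimated correlation). That call ended without neuron 1 (adjusted p = 0.0723), neuron 2 (0.0775) or astrocyte 1 (0.0528), with median-of-ratios scaling (0.0530), with array weights (0.0582) and with length and GC correction (0.0552). Myeloid transcription factors (adjusted p = 0.426), Toll-like receptors and inflammasome genes (0.822, median -0.10 with a test direction of higher), and disease-associated microglia genes (0.207) did not pass. Nor did mature oligodendrocyte markers (adjusted p = 0.354, with 2 of 12 genes higher and 0 adjusted over the list alone) and fibroblast and meningeal markers (0.0818, and 0.0449 without astrocyte 4). Mural cell markers were higher for 4 of 11 genes, including the smooth muscle actin Acta2 (1303 ± 565 TPM in neurons, 99.6 ± 25.7 in astrocytes), without passing as a list (adjusted p = 0.0520). The list passed with median-of-ratios scaling (0.0338), with the stricter filter (0.0178), and without neuron 1 (0.0369), 3 (0.0452) or 4 (0.0493), astrocyte 4 (0.0346) or microglia 3 (0.0393). Vtn was at 1568 ± 248 and 1553 ± 248.

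The largest differences between neurons and microglia were those of P2ry12, C1qb and Ctss, higher in microglia. P2ry12 (chr3:59216272-59262871), the purinergic receptor of microglial processes, was at 8151 ± 2316 TPM in microglia and 5.09 ± 2.09 in neurons (log2 difference of -10.41, neuron minus microglia, adjusted p = 2.68e-16). C1qb, a chain of complement C1q, was at 19443 ± 3649 and 16.9 ± 7.31 (-10.16, adjusted p = 3.23e-16). Ctss, a lysosomal protease, was at 13441 ± 2243 and 12.1 ± 4.91 TPM (-10.07), and the fractalkine receptor Cx3cr1 at 1546 ± 554 and 1.13 ± 0.804 (-9.50). The myeloid master factor Spi1 was at 264 ± 68.1 and 0.990 ± 0.303 TPM (-7.03), and Irf8 at 169.5 ± 57.9 and 1.01 ± 0.506 (-6.37).

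Among called genes without overlap between groups, Itm2a, Alas2 and Car4 had the largest differences in favour of neurons over microglia. The genes of several neuropeptides were also higher in neurons, by smaller folds. Penk (38.5-fold, adjusted p = 1.43e-10), Npy (37.0-fold), Cck (36.8-fold) and Tac2 (28.5-fold) were higher, as were Snap25 (475 ± 193 TPM against 22.5 ± 16.6) and the NMDA receptor subunit Grin2b (73.3 ± 43.0 against 2.07 ± 4.30, adjusted p = 6.01e-07). The microglia mean of Grin2b rested on library 3 at 9.76 TPM (0.08 to 0.23 in the others). Map2, a dendritic microtubule protein, was at 25.9 ± 8.79 TPM in neurons and 4.15 ± 2.17 in microglia (5.44-fold), whereas its log2 difference from astrocytes (34.9 ± 6.90 TPM) was -0.47 (adjusted p = 0.194). Beside these, the neuron libraries held more vascular transcripts. Itm2a was at 5482 ± 962 TPM in neurons and 53.6 ± 23.5 in microglia (106-fold), the carbonic anhydrase Car4 at 1842 ± 407 and 23.3 ± 9.53 (79.0-fold), and Slco1a4, a transporter of the blood-brain barrier, at 659 ± 143 and 13.4 ± 3.69 (46.2-fold).

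In total 5245 genes differed, 3945 higher in neurons and 1300 higher in microglia, so 75.2% were higher in neurons. That split depended on scaling. With median-of-ratios scaling the counts were 2641 and 2130 (55.4% higher in neurons), with quantile normalization 2447 and 1952 (55.6%), and with length and GC correction and library centring 55.8%. These scalings moved the median log2 difference of all genes by -0.52, -0.45 and -0.45 from 0.48, and those of the astrocyte and microglia comparison below by -0.55, -0.52 and -0.52 from 0.57. Dropping the expression filter moved the 2 medians by -0.26 and -0.28, and a pseudocount of 0.1 moved the astrocyte and microglia median by 0.14. At least 8-fold differences were seen for 515 genes in favour of neurons and 375 in favour of microglia. Leaving out the microglia libraries 1 and 2, which held the most oligodendrocyte transcripts, gave 4139 and 1456 genes. Without all libraries numbered 1 and 2 there were 4437 and 1346, and without those numbered 3 and 4 there were 3560 and 1332.

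Most lists of myeloid genes were higher in microglia than in neurons. All 24 microglia markers (median -9.14, adjusted p = 7.76e-36) and all 9 border macrophage markers (-4.29, adjusted p = 7.65e-13) were higher in microglia, each with adjusted p = 0.0411 with an estimated correlation. The same held for 17 of 19 genes of complement, Fc receptors and phagocytosis (adjusted p = 7.26e-22, and adjusted p = 0.0411 with an estimated correlation). Trem2, a lipid receptor of phagocytes, was at 2497 ± 623 TPM in microglia and 2.36 ± 0.953 in neurons. Axl went in the other direction (17.1 ± 4.60 TPM in neurons, 4.39 ± 1.81 in microglia). All 17 Toll-like receptors and inflammasome genes (adjusted p = 1.34e-17), 19 of 21 lysosome genes (adjusted p = 1.01e-21) and 13 of 14 myeloid transcription factors (adjusted p = 2.44e-15) were higher in microglia, each with adjusted p = 0.0790 with an estimated correlation. Among them were Tlr7 (52.8 ± 11 TPM against 0.0420 ± 0.0460), a sensor of single-stranded RNA, and the lysosomal glycoprotein Cd68 (2273 ± 668 against 11.8 ± 4.23). Disease-associated microglia genes were higher in microglia for 10 of 13 (adjusted p = 3.65e-07, and adjusted p = 0.0545 with an estimated correlation). They included the chemokine Ccl6 (749.8 ± 159 TPM against 3.19 ± 1.64), Apoe (9169 ± 1364 against 2290 ± 425) and Cd63 (1072 ± 117 against 415 ± 54.2). Spp1, a secreted phosphoprotein that vascular and meningeal cells also make, was higher in neurons (112 ± 66.5 against 20.2 ± 5.61 TPM).

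Oligodendrocyte transcripts entered the microglia comparison. Mature oligodendrocyte markers were higher in microglia for 7 of 12 genes, or 6 adjusted over the list alone (median -2.69, adjusted p = 0.00122, and adjusted p = 0.502 with an estimated correlation). The call ended with microglia 1 and 2 left out (adjusted p = 0.0602), with median-of-ratios scaling (0.0784), with quantile normalization (0.0673) and with fry (0.0768). Mbp (chr18:82475146-82585637), the myelin basic protein, ranged from 137 to 49353 TPM between microglia libraries and did not pass (-2.94, adjusted p = 0.106). It passed with the replicate number as a block (-2.94) and without neuron 1 (-3.77), neuron 2 (-3.85) or microglia 4 (-4.26). Mag was at 340.3 ± 337 and 24.8 ± 20.5 TPM (-3.49, adjusted p = 0.00342), a call lost with microglia 1 and 2 left out (-2.14). Oligodendrocyte precursor markers were higher in neurons for 9 of 12 genes, such as Lhfpl3 (23.4 ± 10.6 against 1.04 ± 0.313 TPM), without passing as a list (adjusted p = 0.126). They passed without neuron 3 (adjusted p = 0.0374), with microglia 1 and 2 left out (0.0182) and with 2 scalings (0.0240 and 0.0363).

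Neuronal lists were higher in neurons than in microglia. All 18 pan-neuronal markers were higher (median 3.55, adjusted p = 9.08e-05, and adjusted p = 0.424 with an estimated correlation). So were 15 of 16 inhibitory neuron markers (adjusted p = 6.48e-05, and adjusted p = 0.287 with an estimated correlation) and 21 of 23 ionotropic glutamate and GABA receptors (adjusted p = 2.70e-05, and adjusted p = 0.408 with an estimated correlation). For 21 of 22 genes of synaptic vesicle release machinery the difference favoured neurons (adjusted p = 0.00181, and adjusted p = 0.498 with an estimated correlation), with the exception of Syngr1 at 621 ± 187 TPM in microglia against 18.9 ± 2.77. Excitatory neuron markers were higher for 11 of 15 (adjusted p = 0.0103, and adjusted p = 0.391 with an estimated correlation), a call that ended under the stricter filter (0.128). Neuronal transcription factors were higher for 8 of 10 (adjusted p = 0.0213, and adjusted p = 0.417 with an estimated correlation), a call that ended under the stricter filter (0.101) and with length and GC correction (0.0512). Mef2c, which microglia also use, was higher in microglia (337 ± 98.3 against 156 ± 41.3 TPM, -1.10), and this was lost without neuron 2 (-0.92) or microglia 4 (-0.97). Voltage-gated channels were higher for 12 of 16 (adjusted p = 0.0268, and adjusted p = 0.532 with an estimated correlation), a call that ended with length and GC correction (0.0824). In the same libraries all 13 endothelial markers were higher (median 4.58, adjusted p = 1.87e-07, and adjusted p = 0.265 with an estimated correlation). So were 10 of 11 mural cell markers (adjusted p = 1.07e-04, and adjusted p = 0.320 with an estimated correlation) and 6 of 9 fibroblast and meningeal markers. The fibroblast list's adjusted p = 0.0291 became adjusted p = 0.502 with an estimated correlation, 0.0589 with array weights and 0.0504 with microglia 1 and 2 left out.

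Metabolic and astroglial lists gave mixed results between neurons and microglia. Nuclear-encoded oxidative phosphorylation was higher in neurons for 15 of 26 genes (median 1.09, adjusted p = 0.00126, and adjusted p = 0.417 with an estimated correlation), and the call ended with median-of-ratios scaling (0.0539). All 13 endothelial markers were higher in these neuron libraries too (median 4.58). Astrocyte markers were lower in neurons for 7 of 22 and higher for 3 (median -0.44, adjusted p = 0.00131, and adjusted p = 0.424 with an estimated correlation). Aldoc was at 89.7 ± 76.4 TPM in neurons and 303 ± 125 in microglia. Glycolysis (9 of 17 higher and 3 lower, adjusted p = 0.114), fatty acid oxidation (5 of 16 higher and 1 lower, 0.250) and astroglial transcription factors (8 of 16 higher, 0.0770) did not pass. Glycolysis passed with the scalings (0.0446 and 0.0141) and without the filter (0.0242). Astroglial transcription factors passed with median-of-ratios scaling (0.0165), without the filter (0.0207), with the smaller pseudocount (0.0412) and without neuron 3 (0.0486). Glutamate, potassium and water handling had 5 of 16 genes higher and 2 lower (adjusted p = 0.337), and its median of 0.05, against a test direction of lower, became -0.39 and -0.50 with the scalings. Cholesterol synthesis had 0 of 18 genes called (adjusted p = 0.426), and its median of 0.13, also against a test direction of lower, became -0.36 and -0.29. Hk2, the inducible hexokinase, was higher in microglia (19.8 ± 5.36 TPM against 0.154 ± 0.114 in neurons, -4.13).

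The largest difference between astrocytes and microglia was that of Selplg, higher in microglia. In favour of astrocytes, Gja1, the main astrocytic connexin, was at 1597 ± 496 TPM in astrocytes and 12.8 ± 2.75 in microglia (113-fold, adjusted p = 2.46e-14). The coagulation factor receptor F3 was at 1824 ± 318 and 20.5 ± 4.12 (85.1-fold) and Mfge8, an adaptor for phagocytosis, at 5340 ± 1051 and 61.3 ± 8.72 (84.9-fold, adjusted p = 4.09e-15). Clu, a secreted chaperone, was at 16072 ± 720.2 and 272 ± 62.6 TPM (60.2-fold). Selplg (chr5:113818536-113832644), the P-selectin ligand, was at 5320 ± 1491 TPM in microglia and 2.94 ± 0.747 in astrocytes (log2 difference of -10.37, astrocyte minus microglia, adjusted p = 3.61e-16). Gpr34 (2458 ± 730.5 against 2.52 ± 0.857 TPM, -9.43) and Siglech (2817 ± 746 against 3.83 ± 0.808, -9.17) were also higher in microglia.

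In total 5672 genes differed, 4313 higher in astrocytes and 1359 higher in microglia (76.0% higher in astrocytes). The split was 2604 and 2307 with median-of-ratios scaling (53.0%), 2471 and 2048 with quantile normalization (54.7%), and 54.6% with length and GC correction and library centring. At least 8-fold differences were seen for 625 genes in favour of astrocytes and 410 in favour of microglia. With microglia 1 and 2 left out the counts were 4419 and 1479, without all libraries numbered 1 and 2 they were 4860 and 1383, and without those numbered 3 and 4 they were 3811 and 1383. Mature oligodendrocyte markers were higher in microglia for 8 of 12 genes (median -3.04, adjusted p = 1.32e-04, and adjusted p = 0.444 with an estimated correlation), including Mag (-5.30). Their sum varied widely between microglia libraries, from 69940 and 52219 TPM in microglia 1 and 2 to 255 in microglia 4. The last lay below every astrocyte library (470 to 3831 TPM).

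Astroglial lists were higher in astrocytes than in microglia. All 22 astrocyte markers were higher (median 5.01, adjusted p = 1.23e-09, and adjusted p = 0.160 with an estimated correlation), and all 16 astroglial transcription factors (adjusted p = 1.05e-06, and adjusted p = 0.169 with an estimated correlation). So were all 16 genes of glutamate, potassium and water handling (4.71, adjusted p = 2.43e-07, and adjusted p = 0.237 with an estimated correlation). Cholesterol synthesis was higher for 17 of 18 (2.53, adjusted p = 7.75e-04, and adjusted p = 0.502 with an estimated correlation). Fdft1 was at 229 ± 25.9 and 18.1 ± 9.14 TPM, and Ebp went in the other direction (30.4 ± 1.83 and 78.2 ± 6.30). Glycolysis was higher for 15 of 17 (adjusted p = 0.00169, and adjusted p = 0.424 with an estimated correlation), with Hk2 in the other direction (1.19 ± 1.38 and 19.8 ± 5.36). The astrocyte mean of Hk2 was raised by library 3 at 3.65 TPM (0.49 to 0.72 in the others). Fatty acid oxidation was higher for 13 of 16 (adjusted p = 0.00118, and adjusted p = 0.444 with an estimated correlation) and oxidative phosphorylation for 17 of 26 (adjusted p = 4.74e-04, and adjusted p = 0.392 with an estimated correlation). Ionotropic glutamate and GABA receptors were higher for 15 of 23 (adjusted p = 0.00498, and adjusted p = 0.502 with an estimated correlation), led by Gabrg1 (58.3 ± 13.4 against 0.852 ± 0.153 TPM). Endothelial (11 of 13), mural (7 of 11) and fibroblast (9 of 9) markers were higher in astrocytes too (adjusted p = 0.00346, 0.00981 and 0.00319, and adjusted p = 0.498, 0.459 and 0.417 with an estimated correlation).

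Most lists of myeloid genes were higher in microglia than in astrocytes. The 24 microglia markers (median -8.43, adjusted p = 4.32e-34), the 9 border macrophage markers (-3.56, adjusted p = 9.75e-12) and 16 of 19 genes of complement, Fc receptors and phagocytosis (-6.10, adjusted p = 2.07e-18) kept their calls, each with adjusted p = 0.0411 with an estimated correlation. Toll-like receptors and inflammasome genes were higher in microglia for 16 of 17 (adjusted p = 2.59e-16), such as the co-receptor Cd14 (418 ± 120.3 TPM against 1.71 ± 0.280), and so were 13 of 14 myeloid transcription factors (adjusted p = 2.51e-14), each with adjusted p = 0.0790 with an estimated correlation. Tlr3, which senses double-stranded RNA, was higher in astrocytes (29.6 ± 9.88 against 10.2 ± 3.85 TPM, 1.48), a call that ended with both scalings (0.84 and 0.97). Lysosome genes were higher in microglia for 15 of 21 (adjusted p = 6.60e-17, and adjusted p = 0.123 with an estimated correlation). Disease-associated microglia genes were split, with 8 of 13 higher in microglia and 5 higher in astrocytes, among them Apoe (5.75-fold) and Axl (8.17-fold). That list passed toward microglia (adjusted p = 0.00105), with adjusted p = 0.180 with an estimated correlation and 0.0547 with quantile normalization. Several neuronal lists did not pass here: pan-neuronal markers (14 of 18 higher in astrocytes, 15 adjusted over the list alone, adjusted p = 0.126), and excitatory (0.0910) and inhibitory (0.0925) neuron markers. The same was true of synaptic vesicle release machinery (11 of 22 higher, 12 adjusted over the list alone, adjusted p = 0.533), voltage-gated channels (0.476), neuronal transcription factors (0.726) and oligodendrocyte precursor markers (0.823). Pan-neuronal, excitatory and inhibitory neuron markers passed with median-of-ratios scaling (0.0455, 0.0115 and 0.00993), and pan-neuronal markers also with microglia 1 and 2 left out (0.0168).

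Genes higher in a cell type than in both others numbered 1279 for neurons, 1366 for astrocytes and 991 for microglia, 3636 in all, and 5627 tested genes were called in no comparison. Neuron-enriched genes without overlap between groups were ranked by the smaller of their log2 differences from the 2 other cell types. Alas2 came first (5.56), followed by Penk (4.77), Tac2 (4.23), Ly6c1 (4.02), Ly6a (3.97) and Mgp (3.90). Other neuron-enriched genes included Npy, Neurod6, Dlx1 and the calcium sensor Syt1 (42.3 ± 18.7 TPM, against 3.59 ± 0.954 in astrocytes and 1.68 ± 1.19 in microglia). Beside them stood the vascular genes Cldn5 and Ly6c1, the antibacterial gene Pglyrp1 (2182 ± 583, 169 ± 19.3 and 52.1 ± 18.2 TPM) and the matrix protein Mgp (8181 ± 3127, 525 ± 95.2 and 422 ± 167). Astrocyte-enriched genes included Entpd2, which breaks down ATP (155 ± 16.6 TPM, against 2.42 ± 0.792 in neurons and 2.35 ± 0.464 in microglia), the growth factor receptor Fgfr3 (133 ± 42.7, 1.51 ± 0.589 and 1.80 ± 0.622) and Slc39a12, a zinc transporter (285 ± 55.6, 1.21 ± 0.411 and 6.96 ± 1.29). Microglia-enriched genes included P2ry12, Selplg and C1qa (10790 ± 2317 TPM, against 10.8 ± 3.41 and 22.4 ± 3.67). With median-of-ratios scaling microglia-enriched genes numbered 1612. With microglia 1 and 2 left out the 3 counts were 1318, 1355 and 1120. Without all libraries numbered 1 and 2 they were 1315, 1434 and 1032, and without those numbered 3 and 4 they were 1279, 1304 and 1001.

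DNA methyltransferases and their partners were at low levels in all 3 cell types. Dnmt1 (chr9:20907209-20959888), the maintenance methyltransferase, was at 3.77 ± 1.06 TPM in neurons, 2.30 ± 0.547 in astrocytes and 1.67 ± 0.193 in microglia, with log2 differences of TPM + 1 below 1 (0.51, 0.81 and 0.29 for neurons against astrocytes, neurons against microglia and astrocytes against microglia). The second was called with a pseudocount of 0.1 (1.09) and without all libraries numbered 1 and 2 (1.01). Uhrf1 (chr17:56303321-56323486), which brings Dnmt1 to hemimethylated DNA, was at 3.75 ± 1.05 and 2.48 ± 0.784 TPM in neurons and astrocytes and 0.180 ± 0.0721 in microglia. It was higher than in microglia by a log2 of 1.99 in neurons (adjusted p = 1.77e-08) and 1.53 in astrocytes, the latter 0.98 with quantile normalization. Hells (chr19:38930915-38971051), a chromatin remodeller needed for methylation, was higher in neurons (3.14 ± 0.610 TPM) than in microglia (0.390 ± 0.10, log2 1.56, adjusted p = 0.00989), a call that ended with quantile normalization (0.92) and array weights (1.60). Its astrocyte mean of 6.41 ± 11 TPM rested on astrocyte 5 at 26.0 TPM, and the difference from microglia (log2 1.51, adjusted p = 0.0117) was lost without that library (0.82). Dnmt3a (chr12:3806007-3914443), a de novo methyltransferase, was lower in neurons (5.62 ± 0.806 TPM) than in microglia (12.3 ± 1.73, log2 -1.01, adjusted p = 7.81e-04). This was near the 2-fold threshold, and the call was lost without neuron 1 (-0.999) or 2 (-0.93) or microglia 3 (-0.97) or 4 (-0.95), and without ribosomal protein genes (-0.98). Its astrocyte value was 10.5 ± 4.22 TPM. In the neuron libraries these values stood beside the endothelial sum given above.

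The dioxygenases that oxidise 5-methylcytosine were called in no comparison of the main fit, which used a pseudocount of 1. Tet1 (chr10:62804570-62908996) was at 5.01 ± 1.15, 7.86 ± 4.36 and 3.10 ± 0.229 TPM in neurons, astrocytes and microglia, with log2 0.97 for astrocytes against microglia (adjusted p = 0.00334). That value passed 1 without astrocyte 1 (1.08), 2 (1.18) or 5 (1.03) or microglia 4 (1.004), without all libraries numbered 1 and 2 (1.37), or with a pseudocount of 0.1 (1.14). Tet2 (chr3:133463679-133545139) was at 7.18 ± 2.78, 9.12 ± 3.14 and 7.85 ± 2.16 TPM, and Tet3 (chr6:83362373-83459084) at 5.62 ± 0.711, 4.97 ± 1.57 and 4.16 ± 0.330. Idh1 and Idh2, which make the dioxygenase cofactor 2-oxoglutarate, were higher in astrocytes than in neurons (133 ± 20.9 against 35.1 ± 1.82 TPM, 3.66-fold, and 281 ± 27.7 against 72.4 ± 18.3, 3.92-fold). The glycosylase Tdg, which removes oxidised bases, was at 16.4 ± 3.96 TPM in neurons, 19.9 ± 5.36 in astrocytes and 6.76 ± 0.741 in microglia. Its differences from microglia (log2 1.14 and 1.40) were 0.58 and 0.77 with median-of-ratios scaling. The cytidine deaminases Apobec1 (32.8 ± 7.95 TPM in microglia, 5.78 ± 0.267 in neurons and 8.43 ± 1.08 in astrocytes) and Apobec3 (36.0 ± 10.4, 12.4 ± 2.86 and 12 ± 4.03) were higher in microglia. Among readers, Mbd2 was at 27.4 ± 1.64 and 32.0 ± 4.33 TPM in neurons and astrocytes and 11.8 ± 1.51 in microglia (log2 1.16 and 1.37 from microglia, and 0.58 and 0.72 with median-of-ratios scaling).

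None of these 3 lists passed in any comparison. For DNA methyltransferases and maintenance factors the adjusted p was 0.538, 0.839 and 0.876 in neurons against astrocytes, neurons against microglia and astrocytes against microglia. For 5-methylcytosine oxidation and demethylation it was 0.109, 0.670 and 0.462, and for methyl-CpG binding readers 0.363, 0.657 and 0.755. The median of the methyltransferase list for astrocytes against microglia was 0.29, with a test direction of lower, and turned to -0.16 and -0.33 with the scalings. That of the readers was 0.26, also with a test direction of lower, and turned to -0.32 with each. The 5-methylcytosine oxidation list had a median of 0.48 and a mean of 0.35 for neurons against microglia, again with a test direction of lower, and turned to -0.12 with quantile normalization. With fry, which asks whether a list moves on balance and not whether it differs from other genes, adjusted p = 0.00190 was obtained for the oxidation list, lower in neurons than in astrocytes, and 9.15e-05 for that list, higher in astrocytes than in microglia. With fry the methyltransferase list was also higher in neurons (adjusted p = 0.00182) and astrocytes (0.0191) than in microglia, and so was the list of readers (4.52e-04 and 0.0149).

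**Figure D3:**
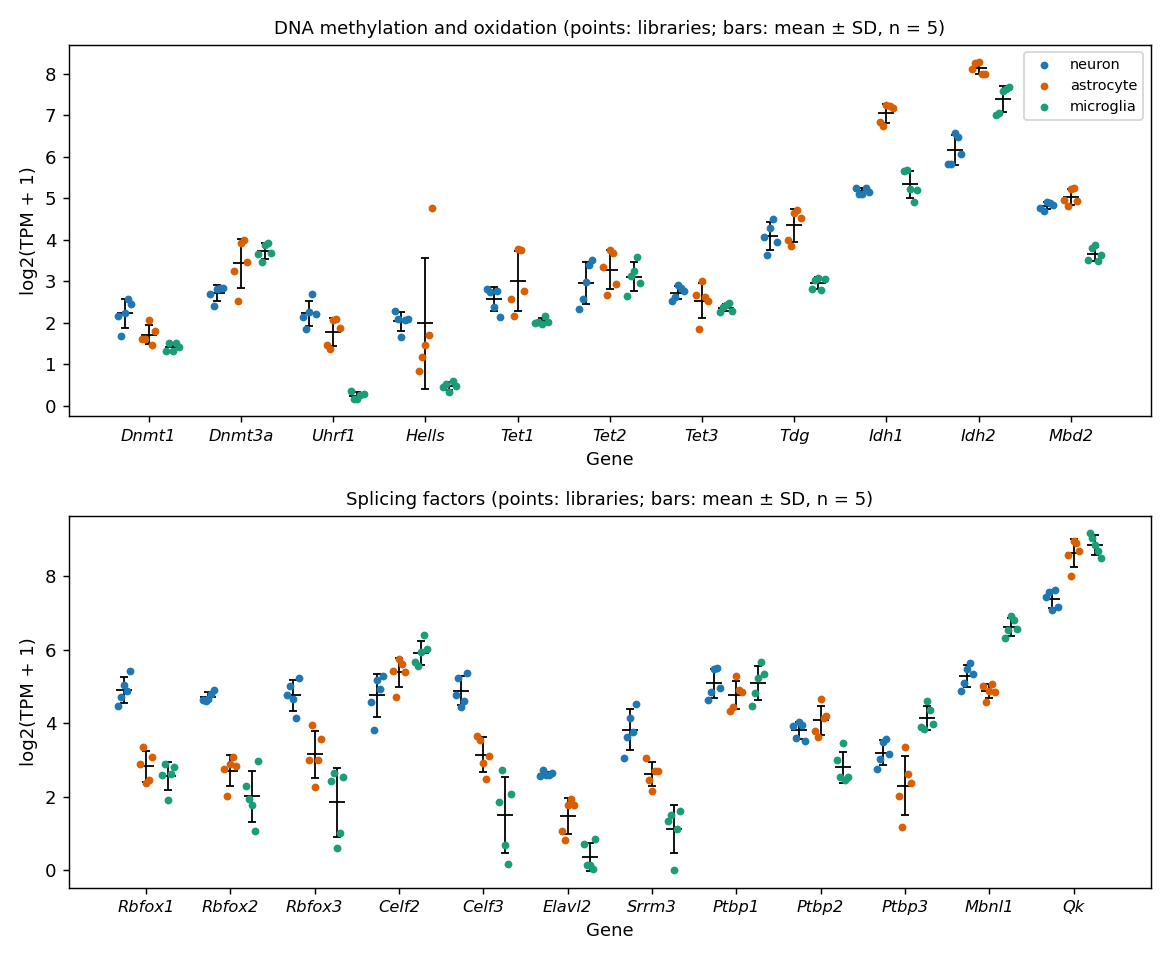
log2(TPM + 1) of 11 DNA methylation genes and 12 splicing factors in the 15 libraries. Points are libraries and bars are means ± SD, n = 5.

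The splicing regulators Rbfox1, Rbfox2, Rbfox3 and Celf3 were higher in neurons than in both other cell types. Rbfox1 (chr16:5885355-7411526) was at 29.7 ± 7.77 TPM in neurons, 6.37 ± 2.13 in astrocytes and 5.11 ± 1.42 in microglia (4.21-fold and 5.04-fold, adjusted p = 6.74e-07 and 7.23e-08), and Rbfox2 at 25.4 ± 2.30, 5.77 ± 1.65 and 3.43 ± 2.16 (4.01-fold and 6.53-fold). Rbfox3 (chr11:118489762-118911597), the antigen of the NeuN antibody, was at 27.1 ± 7.64, 8.62 ± 4.10 and 3.19 ± 2.23 TPM (3.05-fold and 7.56-fold), and Celf3 at 29.5 ± 8.57, 8.22 ± 2.92 and 2.45 ± 2.21 (3.35-fold and 10.4-fold). Srrm3, a regulator of microexons, was at 14.0 ± 5.57, 5.28 ± 1.45 and 1.34 ± 0.818 TPM. Its difference from astrocytes (log2 1.21, adjusted p = 0.00258) was no longer called with a pseudocount of 0.1 (1.34). Elavl2 was at 5.19 ± 0.254, 1.92 ± 0.915 and 0.336 ± 0.366 TPM, and its difference from astrocytes (log2 1.15) ended without astrocyte 2 (0.99) and with array weights (0.99). Endothelial markers were higher in the same neuron libraries by a median of 2.60 against astrocytes and 4.58 against microglia.

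Among other splicing factors, Qk, Mbnl1, Ptbp3 and Celf2 were higher in a glial cell type in at least 1 comparison. Qk, an RNA-binding protein of glia, was at 405 ± 94.6 TPM in astrocytes, 468 ± 86.9 in microglia and 167 ± 27.2 in neurons (log2 -1.25 and -1.47, neurons minus each). Mbnl1 was at 98.8 ± 16.5 TPM in microglia, 38.7 ± 8.21 in neurons and 28.6 ± 3.78 in astrocytes. Ptbp1, a repressor of neuronal exons, was at 34.0 ± 9.48, 27.0 ± 7.60 and 34.7 ± 11.1 TPM in neurons, astrocytes and microglia. Ptbp3 was higher in microglia (16.9 ± 4.28 TPM) than in astrocytes (4.57 ± 2.96, log2 -1.83). Celf2 was higher in microglia (60.8 ± 14.7 TPM) than in neurons (27.8 ± 9.99, log2 -1.16), a call lost without neuron 2 (-0.92). The list of tissue-regulated splicing factors was higher in neurons than in astrocytes for 7 of 28 genes, or 8 adjusted over the list alone, and lower for 1 (median 0.56, adjusted p = 0.0190, and adjusted p = 0.424 with an estimated correlation). The call ended with median-of-ratios scaling (0.0516) and with the stricter filter (0.169). Against microglia the list had 16 genes higher in neurons and 3 lower (adjusted p = 0.207), and between astrocytes and microglia 10 and 2 (0.900).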

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

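Chosen only after the results were seen were both tests of swapped libraries and the best match of replicate numbers. The vascular, replicate-number and oligodendrocyte patterns below were themselves found in these data. The other tests of them had predictions written before their results were seen, but were chosen because of those patterns.

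Endothelial markers summed to 32729 ± 5025 TPM in the neuron libraries (n = 5), against 2507 ± 263 in astrocytes and 597 ± 193 in microglia. Of the 20 genes in a further endothelial list, 95% (19 of 20) were higher in neurons than in both other cell types. Of all tested genes 9.58% were. This was the outcome predicted for RNA of vascular cells in the neuron isolate. However, all 13 genes of the first list were already higher, and genes of the same cell type tend to move together. Expression of these genes by the neurons themselves would give the same outcome, so the list does not part the 2 sources. A swap of libraries was argued against, as 5 of 5 neuron libraries exceeded all 10 others in the pan-neuronal sum (lowest 1998, highest other 875 TPM). These sums were known before the check was chosen, so it says nothing further on the source of the vascular transcripts. Whether the neurons themselves expressed these genes was not decided by a test of the 2 sums. The log2 ratio of endothelial to pan-neuronal sums varied 0.724 times as much as the log2 pan-neuronal sum. A negative relation of the 2 sums had a one-sided exact permutation p of 0.817, and 5 libraries cannot decide the question by this test. The endothelial sum also mostly follows 1 gene with uncertain reads, Ly6c1, at 31922 of 40984 TPM in neuron 5 and 20119 to 21722 in the others. By mean log2(TPM + 1) of the endothelial markers, neuron 5 (7.77) lay below neurons 3 (8.07) and 4 (8.14). Markers of other non-neuronal cells were high in the neuron libraries as well. The mural sum was 4281 ± 1104 TPM, with 4 of 11 genes higher than in astrocytes and 10 of 11 higher than in microglia. Alas2 was at 451 ± 315 TPM, against 7.41 ± 2.23 in astrocytes and 3.04 ± 2.05 in microglia. These values do not test the source of the endothelial transcripts. No purity measure of the isolates is in the labels.

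Libraries numbered 1 and 2 differed from those numbered 3 and 4 alike in the 3 cell types, with correlations of this difference across 13333 genes of 0.286, 0.456 and 0.307. After correction for transcript length and GC content they were 0.300, 0.453 and 0.302, the lowest 0.300, which argues against length or GC content as the whole source, although in astrocytes the difference followed length (rho -0.399) and GC content (0.200). A difference in animal or handling day carried by the replicate number cannot be told apart from other sources: a library matched best with its own number in 8 of 15 comparisons, and no label gives animals or days. Immediate early and dissociation-response genes differed by a median log2 of -0.97 in neurons, -0.21 in astrocytes and -1.12 in microglia, being lower in 22, 13 and 22 of 23 genes in the libraries numbered 1 and 2. No biological explanation was tested, as the design gives no group within a cell type.

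Oligodendrocyte transcripts varied widely between microglia libraries, with Mbp at 49353, 32254, 3425, 137 and 5902 TPM in libraries 1 to 5. It was at 6914, 8844, 36.7, 66.6 and 1077 TPM in neuron libraries, and at 822, 3251, 365, 237 and 947 in astrocyte libraries. In each cell type Mbp was higher in both libraries numbered 1 and 2 than in those numbered 3 and 4, so its variation followed the split by number described above. A swap of libraries was argued against, as 5 of 5 microglia libraries exceeded all 10 others in the sum of microglia markers. That outcome was known from the marker sums before the check was chosen, so it says nothing further on where the oligodendrocyte transcripts came from. Other sources of this variation were not told apart, and no label describes the makeup of the isolates. No biological explanation was tested, as no group of the design separates these libraries.

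The numbers of called genes were compared with those of regrouped libraries in 100 splits, the real one included. Every other split mixes cell types that are already far apart, which widens the spread within groups. Fewer calls there were therefore largely fixed in advance and say nothing on vascular or oligodendrocyte RNA in the isolates. For neurons and astrocytes 1 of 100 splits reached 3412 genes, the real one, and the highest other called 1. For neurons and microglia 1 of 100 reached 5245 and the highest other 2706. All 16 possible splits that part all 5 pairs of equal numbers were also fitted, the real one included, and the highest other among them was again 2706. For astrocytes and microglia 1 of 100 reached 5672, with 2621 as the highest other, and for enriched genes 1 of 100 reached 3636, with 1014 as the highest other. The number of list tests past the threshold, 71, was reached by 5 of 100 splits, the highest at 78. A regrouping of libraries was thus not excluded as a source of that number. Regrouped libraries can still differ in their mix of cell types. The splits therefore cannot show how many list tests would pass without cell type differences.

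A library outlying by Dixon's rule (critical value 0.71) was found in 26 of 567 groups of 5 libraries, against 28.4 expected at 1 in 20. Among neurons, Ly6c1 was at 31922 TPM in library 5 (20119 to 21722 in the others), Sst at 366.9 in library 5 (91.0 to 128), Gpr37l1 at 21.6 in library 3 (56.9 to 83.6), Gabrg1 at 0.71 in library 3 (1.32 to 1.47), Hapln1 at 2.51 in library 4, Tlr3 at 8.13 in library 4 and Hopx at 35.0 in library 2. The neuron sum of synaptic vesicle release machinery was 2096 in library 5 (1182 to 1346). Among astrocytes, Hells was at 26.0 TPM in library 5 (0.77 to 2.24), Cd79a at 1.4 in library 5, Acta2 at 144.8 and Syngr1 at 67.3 in library 4, Hk2 at 3.65 in library 3, Klf2 at 22.5 in library 2 and Cd3d at 0.04 in library 1. Astrocyte sums were 2042 for endothelial markers in library 2 (2577 to 2666) and 31626 for glycolysis in library 5 (29457 to 30057). Among microglia, Grin2b was at 9.76 TPM in library 3 (0.08 to 0.23), S100a9 at 179.8 in library 5 (387 to 514), Slc39a12 at 9.21 in library 5, Tac2 at 1.02 and Axl at 7.62 in library 2, and Hopx at 13.7 and Tet1 at 3.49 in library 4. Microglia sums were 1909 for border macrophage markers in library 3 (1293 to 1408) and 9.05 for ionotropic glutamate and GABA receptors in library 4 (20.2 to 24.7).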

How the results depend on the processing

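Chosen only after the data were seen were 5 alternatives: microglia 1 and 2 left out, numbers 1 and 2 left out, numbers 3 and 4 left out, and 2 corrections for length and GC content with the replicate block. Without numbers 1 and 2, 10 calls of named genes ended and 14 were gained, and 4 list calls ended and 1 was gained. Without numbers 3 and 4, 22 calls of named genes ended and 6 were gained, and 5 list calls were gained. Scaling moved the most counts. Genes higher in neurons than in microglia (3945) numbered 2447 with quantile normalization and 2489 with length and GC correction and library centring, and genes higher in microglia (1300) numbered 2130 with median-of-ratios scaling, 1952 with quantile normalization and 1972 with the centring correction. Genes higher in astrocytes than in microglia (4313) numbered 2604, 2471 and 2544 in that order, and genes higher in microglia (1359) numbered 2307, 2048 and 2113. Microglia-enriched genes (991) numbered 1612 with median-of-ratios scaling and 1491 with the centring correction. The cause was not tested. The length and GC correction that keeps each library's mean gave 1738, 1686, 3947, 1316, 4319 and 1372 genes and 69 list tests, while an earlier version could not move group means and was dropped. With the replicate number as a block the counts were 1743, 1690, 3948, 1308, 4330 and 1364, with 73 list tests. The block brought calls for Mbp between microglia and each other cell type, for Mag and Cox6c (log2 1.05, adjusted p = 0.0520 without it) between neurons and astrocytes, and, between neurons and microglia, the interferon response (adjusted p = 0.0382) and ribosomal protein (0.0390) lists, and changed no other call among named genes and lists. With one library left out, counts ranged over 1639 to 1816 and 1538 to 1860 for neurons against astrocytes, 3820 to 4076 and 1269 to 1378 for neurons against microglia, 4123 to 4529 and 1312 to 1416 for astrocytes against microglia, and 69 to 74 for list tests. No call of a named gene turned direction under any alternative. List tests past the threshold (71) numbered 7 with an estimated correlation and 97 with fry. Between astrocytes and microglia fry gave the opposite direction for DNA methyltransferases and maintenance factors (adjusted p = 0.0191) and methyl-CpG binding readers (adjusted p = 0.0149).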

Other observations

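Interferon-response and antigen presentation genes differed between the cell types. Isg15, a ubiquitin-like protein induced by interferon, was at 154 ± 46.1 TPM in neurons, 31.9 ± 20 in astrocytes and 18.8 ± 8.51 in microglia (n = 5), and Ifitm3, a membrane protein that restricts viral entry, at 5104 ± 1548, 1130 ± 173 and 657 ± 169.8. Interferon response genes were higher in neurons than in astrocytes for 11 of 15 (median 1.57, adjusted p = 2.07e-05, and adjusted p = 0.417 with an estimated correlation). Against microglia the list did not pass (median 1.96, adjusted p = 0.0639) but did with the replicate block (adjusted p = 0.0382), with the scalings (0.0190 and 0.0145) and without neuron 5 (0.0364) or astrocyte 3 (0.0342). Ifi27l2a was the exception there, higher in microglia (197 ± 50.3 TPM against 56.6 ± 23.1). Between astrocytes and microglia the list did not pass (adjusted p = 0.289), and its median of 0.57 was near 0 with the scalings. MHC class II presentation was higher in microglia than in neurons for 6 of 6 genes (median -4.07, adjusted p = 2.91e-07, and adjusted p = 0.157 with an estimated correlation) and than in astrocytes (-5.45, adjusted p = 3.16e-08, and adjusted p = 0.123 with an estimated correlation). It was higher in neurons than in astrocytes for 5 of 6 (adjusted p = 0.00773, and adjusted p = 0.424 with an estimated correlation). Cd74, the invariant chain, was at 596 ± 66.6 TPM in microglia, 39.7 ± 18.9 in neurons and 9.68 ± 4.44 in astrocytes. In the same neuron libraries the endothelial sum was 32729 ± 5025 TPM. The microglia libraries also held border macrophage (1457 ± 257 TPM) and blood leukocyte (845 ± 280 TPM) markers. Which cells gave their MHC class II transcripts was not tested.

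Ribosomal protein, cell cycle and immediate early transcripts were higher in neurons than in astrocytes. Ribosomal proteins took 6.23 ± 0.986% of all TPM in neurons, 2.50 ± 0.436% in astrocytes and 3.90 ± 0.587% in microglia, with Rpl32 at 1525 ± 375, 437 ± 127 and 1058 ± 168 TPM. The list was higher in neurons than in astrocytes for 22 of 28 genes (median 1.19, adjusted p = 4.75e-13, and adjusted p = 0.237 with an estimated correlation) and lower in astrocytes than in microglia for 3 of 28 (-0.60, adjusted p = 6.01e-10, and adjusted p = 0.320 with an estimated correlation). Between neurons and microglia it did not pass (0.57, adjusted p = 0.113, and adjusted p = 0.0390 with the replicate block), with a median of -0.04 after median-of-ratios scaling. Cell cycle genes were higher in neurons than in astrocytes for 7 of 14 (adjusted p = 1.98e-05, and adjusted p = 0.391 with an estimated correlation) and than in microglia for 12 of 14 (adjusted p = 2.18e-04, and adjusted p = 0.417 with an estimated correlation). Birc5, an inhibitor of apoptosis in dividing cells, was at 43.1 ± 12.4, 11.5 ± 2.13 and 2.39 ± 0.992 TPM, and the list did not pass between astrocytes and microglia (adjusted p = 0.109, and 0.0458 with median-of-ratios scaling). Immediate early and dissociation-response genes were higher in neurons than in astrocytes for 11 of 23 (adjusted p = 4.86e-04, and adjusted p = 0.502 with an estimated correlation) and higher in microglia than in astrocytes for 12 of 23 (adjusted p = 2.41e-06, and adjusted p = 0.417 with an estimated correlation). Against neurons they were higher in microglia for 8 and lower for 5 (adjusted p = 0.0163, adjusted p = 0.623 with an estimated correlation, 0.660 with fry, and 0.131 and 0.154 with the scalings). Within neurons and within microglia 22 of these 23 genes were lower in the libraries numbered 1 and 2 than in those numbered 3 and 4 (median log2 -0.97 and -1.12), against 13 in astrocytes (-0.21). Junb was at 564 ± 293 TPM in microglia and 73.9 ± 59.4 in neurons, and Klf2, a shear-stress factor of endothelium, at 12.7 ± 6.95 and 163 ± 48.8. In the same neuron libraries all 13 endothelial markers were higher than in each other cell type, with a sum of 32729 ± 5025 TPM against 2507 ± 263 in astrocytes and 597 ± 193 in microglia.

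Blood leukocyte markers were higher in neurons than in astrocytes for 7 of 10 genes (adjusted p = 0.00439, and adjusted p = 0.417 with an estimated correlation) and higher in microglia than in astrocytes for 7 (adjusted p = 7.95e-06, and adjusted p = 0.169 with an estimated correlation). Between neurons and microglia 3 were higher and 5 lower (adjusted p = 0.00846, adjusted p = 0.417 with an estimated correlation, and 0.150 and 0.0975 with the scalings). S100a9, a neutrophil protein, was at 405 ± 134 TPM in microglia and 10.3 ± 3.58 in neurons, and the B cell gene Cd79a at 0.954 ± 0.555 and 8.13 ± 4.38. The neuron libraries were also higher than astrocytes in endothelial (32729 ± 5025 against 2507 ± 263 TPM) and mural (4281 ± 1104 against 2266 ± 311) sums and in Alas2 (451 ± 315 against 7.41 ± 2.23). Ependymal and choroid plexus markers passed in no comparison (adjusted p = 0.426, 0.102 and 0.0823 for neurons against astrocytes, neurons against microglia and astrocytes against microglia), the last 2 being 0.0272 and 0.0186 with median-of-ratios scaling.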
